A study of Canis lupus familiaris with 8 samples.

How the data were processed

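RNA sequencing of messenger RNA was deposited for 8 libraries, adrenal cortex and pituitary of adult Beagle and Chinese Field Dog, each stressed or unexposed, with 1 library per combination. The group label names one arm as treated with chronic stress exposure and the other as treated with non-disposal, which was read here as the unexposed arm. The extraction note of the labels speaks of spleen, while tissue names and titles give adrenal cortex and pituitary, which were used. Per the labels, libraries were made with the TruSeq kit and sequenced on the Genome Analyzer IIx, and reads were aligned by the authors with TopHat, version not stated, to CanFam3.1. The program that counted reads and the gene annotation were not stated.

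The deposited files were 8 tables, each setting 2 libraries against each other over 24580 Ensembl genes, of which 18986 had a symbol and 16080 a symbol used once. Each table gave a scaled count and an FPKM per library, and each library's columns were identical in every table that held it (16 of 16 pairs compared). The authors' FPKM values are read counts corrected for gene length and depth, with 1 scaling over all libraries. The authors' scaled counts are a signal per gene, whose values are whole multiples of 1 step per library, so that they are read counts divided by 1 size factor. The p-value and FDR columns are the authors' own, with equal FDR for equal p-values in every table, so that the adjustment covered all tables together. The log2 columns are the authors' ratios of FPKM, with 1 or -1 written where both values were 0, and 0 against a value above 0 mostly replaced by 0.1 or 1. These authors' results are reported once, as the authors' deposited table, and nothing else rests on them.

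Reads were recovered by dividing each scaled count by its library's step, which was worth 0.899 to 1.17 units. Between 97.6% and 99.1% of values were then whole within 0.02. For the stressed Beagle adrenal cortex and the stressed Chinese Field Dog pituitary, whose step was close to 1, recovered reads are taken as near the true counts and not as exact. Recovered reads per library ranged from 14327357 to 18712041, and the 10 most abundant genes held 9.6% to 15.8% of them. Intervals on ratios are 95% Clopper-Pearson intervals on recovered reads, intervals on shares are Wilson intervals, and a count of 0 allows up to 3 reads. A fold against 0 reads is not given. GH1 and RRBP1, marked by the authors as failed in the unexposed Beagle pituitary and listed there at 0, were kept in the counts and named where they enter.

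Per comparison of 2 libraries, log2 ratios were taken after adding 1 to each FPKM, over genes with a mean FPKM of at least 1, and genes with a log2 ratio of at least 1 in size were counted as 2-fold different. No test was possible for such a pair. Genes were tested with limma 3.58.1 in R 4.3.3 on 4 log2 ratios, 2 per tissue, with 1 coefficient per tissue and 2 residual degrees of freedom, so that the breeds served as replicates of the stress effect and the exposures as replicates of the breed effect. P-values were adjusted by Benjamini and Hochberg over all genes of a contrast, with a threshold of 0.05. Calls were also adjusted over each list alone, a family of 120 list tests in 4 contrasts, with no correction across lists. Members of a list can vary together within a library, so calls within a list are not independent of each other. Nothing states whether libraries come from separate animals or from pools, so these p-values measure only the spread between these samples. Simulated data held 50 changed genes at each of 2-, 4-, 8- and 16-fold. Limma recovered 0 to 2 of the 50 at 2-fold, 29 to 42 at 4-fold and 48 to 50 at 8-fold, with 6 to 16 calls among unchanged genes. The simulated spread was a fixed setting and was not estimated from these libraries, so recovery in the real data may differ.

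The medians of 30 gene lists were compared with 10000 random lists matched on abundance in 20 bins. The lists were anterior pituitary hormones, corticotroph, pituitary receptors, pituitary lineage factors, secretory granule, steroid synthesis, cholesterol synthesis and uptake, zona glomerulosa and capsule, immediate-early, glucocorticoid receptor targets, heat shock, endoplasmic-reticulum stress, oxidative stress, interferon response, inflammatory, antigen presentation, proliferation, nuclear respiration genes, ribosomal proteins, adrenal medulla, neural with glial and posterior-lobe, erythroid, lymphocyte, macrophage and neutrophil, endothelial, fibroblast and matrix, adipocyte, muscle, liver and kidney, and sex-linked genes. Another 9 lists were written after the values were seen: cortical neuron, hypothalamic neuropeptide, posterior lobe, melanotroph, hepatocyte, macrophage, T and natural killer cell, and class I and class II antigen genes. Correlations across genes were Pearson's.

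The grouping, the comparisons, the filter, the pseudocount, the 30 lists, the first set of alternatives and the rule for naming genes were fixed before the data were examined. That rule took genes with a symbol of their own and a mean FPKM of at least 1. It named the 5 highest and 5 lowest log2 ratios of each comparison, the 5 that were highest or lowest in both ratios of a contrast by the smaller ratio, and the 5 highest and 5 lowest differences between the breeds' stress ratios. It also named up to 4 members of each list with the widest ratios and all members of the hormone, steroid and corticotroph lists. It returned mostly small RNAs and short gene models on 1 to 3 reads, so the same ranking over genes with at least 100 reads was added after the values were seen, and the ranked genes in the text come from it. Genes outside the rule that are named in the text were chosen after their values were seen.

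Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, ratios centred on the median of genes with at least 5 FPKM, values of the same libraries taken from the other tables with ratios centred, 1 fit per tissue, limma-trend, leaving out each ratio in turn and Spearman's correlation. Alternatives chosen after seeing the data were a filter of at least 50 recovered reads in place of the FPKM filter, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads with additive breed and exposure terms per tissue, and these or the earlier settings applied to list calls, named genes and the breed by exposure difference. Where a ratio was left out, the lone ratio was taken to vary like those of the other tissue. Centring moved ratios by less than 0.1 on the log2 scale. Groups of 1 library leave no test of outlying samples and no regrouping of samples, and the breed by exposure difference had no residual degrees of freedom. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.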

Results

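Messenger RNA was measured in the adrenal cortex and the pituitary, the gland that drives adrenal cortisol through the hormone made from POMC, of adult Beagles and Chinese Field Dogs. One arm of each breed had been exposed to chronic stress and the other had not, and each combination of breed, tissue and exposure held 1 library, so that the 8 libraries formed 8 groups with no replicates. The labels did not say whether a library came from 1 dog or from a pool, nor whether both tissues came from the same dogs. Recovered reads totalled 15803954 in the unexposed Beagle adrenal cortex, 18109559 in the stressed Beagle adrenal cortex, 18712041 in the unexposed Chinese Field Dog adrenal cortex and 16289185 in the stressed one. The pituitary libraries held 14327357 reads in the unexposed Beagle, 15756311 in the stressed Beagle, 15125537 in the unexposed Chinese Field Dog and 15192489 in the stressed one. Each library also limits what a listed value of 0 shows, since a count of 0 allows up to 3 reads. Counting intervals below are 95% Clopper-Pearson intervals on the ratio of recovered reads, and intervals and floors cover counting error only. Values are FPKM, a read count corrected for gene length and sequencing depth, and log2 ratios were taken after adding 1 to each FPKM.

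The first question was what chronic stress changed within each breed and tissue. Genes at least 2-fold different between the stressed and the unexposed library numbered 450 of 13730 in the Beagle adrenal cortex, with 114 higher and 336 lower in the stressed library. The Chinese Field Dog adrenal cortex had 275 of 13634, with 135 higher and 140 lower. The Beagle pituitary had 338 of 14366, with 181 higher and 157 lower, and the Chinese Field Dog pituitary had 1405 of 14720, with 1155 higher and 250 lower. No test lies behind these counts, since single libraries have no spread of their own. Counting error simulated at the same depth counted 72 to 82 unchanged genes as 2-fold different, and between 111 and 117 of the counted genes in each stress comparison had fewer than 10 reads in both libraries. Where genes had to hold at least 50 reads, a filter chosen after the values were seen, the 4 counts were 281, 126, 194 and 1239 in the same order.

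**Figure D1:**
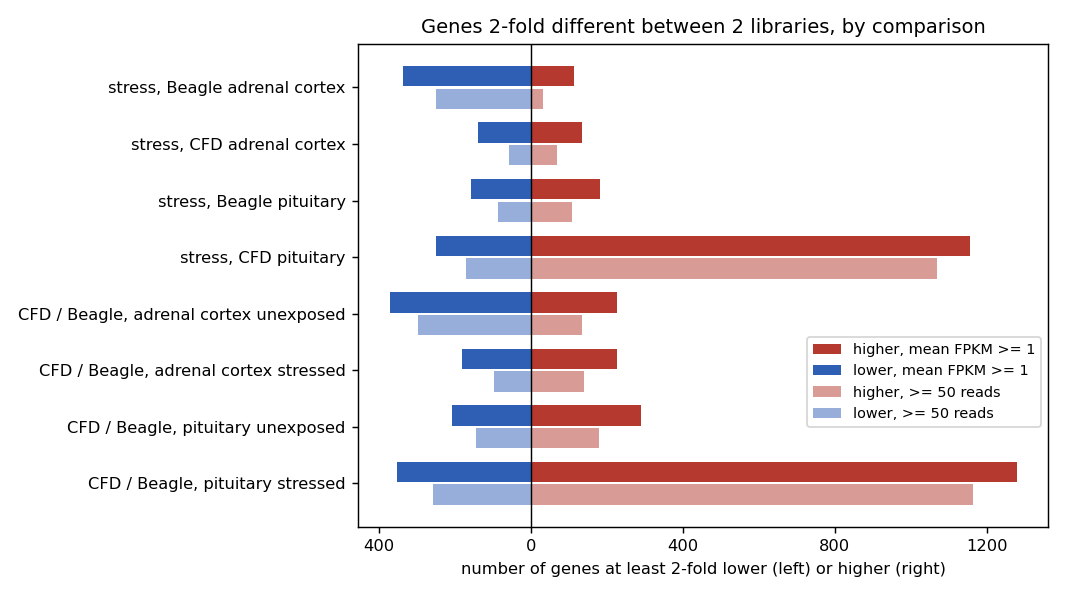
Number of genes at least 2-fold higher or lower (horizontal axis) in each of the 8 comparisons of 2 libraries (vertical axis), dark for genes at a mean FPKM of at least 1 and pale for genes with at least 50 reads; CFD is Chinese Field Dog. By FPKM, the 2 comparisons with the stressed Chinese Field Dog pituitary held 1405 and 1631 genes, mostly higher, against 275 to 598 in the other 6.

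In the Beagle adrenal cortex, transcripts of the adrenal medulla and its nerve-like cells were lower in the stressed library. UCN, a stress peptide related to corticotropin-releasing hormone, read 4.21 FPKM against 51.9 (log2 -3.35, counting interval -4.46 to -2.83). NPY, a neuropeptide stored with catecholamines, read 35.2 against 266 (log2 -2.88), and GAL, the neuropeptide galanin, read 14.3 against 106 (log2 -2.80). Of the 20 measured medulla genes 18 were lower, with a median log2 of -0.63, including the catecholamine enzymes TH (log2 -0.85), DBH (log2 -0.70) and PNMT (log2 -0.72). Genes of fat cells were also lower in 11 of 11 cases (median log2 -1.55), led in abundance by the lipid-droplet gene PLIN1 at 1.51 against 11.9 FPKM. Whether the sampled pieces differed in their share of medulla or fat was not tested. Heat-shock chaperones were lower in 16 of 17 cases (median log2 -0.46), with HSPH1 at 34.8 against 98.6 and DNAJB1 at 15.0 against 40.8. Cholesterol synthesis and uptake genes were lower in 20 of 26 cases (median log2 -0.41), with SQLE, a sterol-synthesis enzyme, at 3.63 against 12.5. Of 14 measured steroid-synthesis genes 7 were higher and 7 lower (median log2 0.02), with CYP17A1 at 4944 against 4949 FPKM, and STAR, the cholesterol carrier of the mitochondrion, at 5079 against 6288. MRAP, partner of the receptor for adrenocorticotropic hormone, read 133 against 407. CYP11B1, CYP11B2, POR, NR5A1 and SULT2A1 were not matched by symbol in any library and were not analysed here. The liver-protein gene ALB had the highest log2 ratio among genes with at least 100 reads, 4.0, at 27.7 against 0.790 FPKM, followed by CORIN, a membrane protease, at log2 2.12.

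In the Chinese Field Dog adrenal cortex, some plasma-protein genes of the liver had the highest ratios and another the lowest. FGG, a fibrinogen chain, read 106 against 9.78 FPKM (log2 3.32, counting interval 3.26 to 3.62), HP, the haemoglobin-binding protein haptoglobin, read 52.5 against 9.13 (log2 2.40), and ALB read 9.09 against 0.121 (log2 3.17). ITIH4, a plasma protease inhibitor, had the lowest ratio among genes with at least 100 reads (log2 -1.96), and the fixed liver and kidney list had 4 genes higher and 3 lower (median log2 0.50). TNMD, a membrane protein of tendon and fat, read 54.4 against 9.90 (log2 2.35). Ribosomal protein genes were higher in 39 of 39 cases (median log2 0.54, random lists of like abundance 0.18 to 0.41). Nuclear genes of mitochondrial respiration were higher in 28 of 28 (median log2 0.37), inside the range of random lists of like abundance (0.11 to 0.37). The medulla genes were lower in 16 cases (median log2 -0.37), with DBH at 239 against 331 FPKM, while TH stood at 134 against 140. Steroid-synthesis genes had a median log2 of 0.21, inside the range of random lists of like abundance (0.0048 to 0.3834). STAR read 7984 against 5494 FPKM and CYP17A1 5308 against 4494. MC2R, the receptor for adrenocorticotropic hormone, read 98.1 against 96.4, while its partner MRAP was lower in the stressed library, as in the Beagle. Cholesterol synthesis and uptake genes were 15 higher and 11 lower (median log2 0.04), inside the range of random lists. Fat-cell genes were higher in 9 of 10 cases (median log2 0.49), the opposite of the Beagle.

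Across both breeds, the adrenal cortex held few genes with a shared stress ratio. ALB (ENSCAFG00000003016, CanFam3.1 chromosome 13, 62152697 to 62169575) was higher in both, and PROM1, a membrane protein of epithelial cells, read 111 against 54.9 in the Beagle and 111 against 18.1 in the Chinese Field Dog. ITIH4 was lower in both at 71.4 against 182 and 44.2 against 175 FPKM, as were MDGA1 (5.32 against 14.2 and 3.93 against 11.9) and the synaptic gene CBLN2 (1.60 against 7.01 and 2.01 against 7.70). Limma, with the breeds as replicates and 2 residual degrees of freedom, called 3 of 13759 genes, SNORA32 and PLN higher and SNORA31 lower, each on 1 read per library at most. At an unadjusted p under 0.05 there were 479 genes against 688 expected by chance. ALB had a log2 of 3.58 (SE 0.30) and an adjusted p of 0.495. With adjustment over the list alone, 2 of 6 measured liver and kidney genes passed, ALB and APOA2, and 0 did so over all genes; leaving out either breed kept the count at 2, but APOA2 rested on at most 9 reads. The 20 medulla genes gave 0 calls over the list alone (14 lower in both breeds, lowest adjusted p 0.0772) and 0 over all genes, with 6 at an unadjusted p under 0.05. Ribosomal protein genes were higher in both breeds in 33 of 39 cases, heat-shock genes lower in both in 11 of 17 and endothelial genes higher in both in 12 of 14, each with 0 calls. Without the Beagle ratio the count over all genes was 40, and without the Chinese Field Dog ratio 30; with at least 50 reads required it was 0, edgeR gave 0 (564 at an unadjusted p under 0.05 of 15901) and DESeq2 gave 11.

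In the Beagle pituitary, most genes that respond to glucocorticoids were lower in the stressed library, as were 17 of 24 immediate-early genes (median log2 -0.38). ERRFI1, a feedback inhibitor of growth-factor receptors, read 9.73 against 37.6 FPKM (log2 -1.85), PDK4, a switch of fuel use, 35.3 against 90.9 (log2 -1.34), and FKBP5, the chaperone that damps the glucocorticoid receptor, 53.6 against 80.3 (log2 -0.57). Of 17 listed glucocorticoid receptor targets 16 were lower (median log2 -0.72), while the receptor gene NR3C1 itself read 25.9 against 31.3. The signal-induced genes DUSP2 (1.32 against 22.4, log2 -3.34, counting interval -4.64 to -3.59) and GADD45G (6.56 against 44.3) were among the 5 lowest of genes with at least 100 reads, as were the airway genes BPIFA1 (log2 -3.27) and SCGB1A1 (log2 -3.12). NR4A1 read 32.2 against 108, and AVPR1B, the vasopressin receptor of corticotrophs, read 1.56 against 4.99. Heat-shock genes were lower in 17 of 17 cases (median log2 -0.28). In both breeds, 6 of 17 heat-shock genes were lower and 0 higher with stress, and of 25 immediate-early genes 7 were lower and 5 higher. TTR, the thyroxine carrier, was higher at 86.3 against 6.69 FPKM (log2 3.51), as were CXCL14 (log2 2.37) and NPY (log2 2.28). Posterior-lobe genes were higher in 4 of 4 cases (median log2 1.01), with OXT, the oxytocin gene, at 69.8 against 21.0. Melanotroph genes had a median log2 of 0.16, inside the range of random lists, with PAX7 at 10.1 against 4.93 but DRD2 (log2 0.09) and TBX19 (log2 -0.08) near their unexposed levels. Hormone genes differed little, with POMC at 26580 against 23760, PRL at 31810 against 31610 and TSHB at 892 against 813 FPKM. GH1 and RRBP1 were listed at 0 in the unexposed Beagle pituitary because the authors' estimate had failed, so no fold is given for them, although both are among the 338; the median log2 of the hormone genes was 0.14 with GH1 (7 genes) and 0.14 without it (6 genes).

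In the Chinese Field Dog pituitary, genes of forebrain neurons were far higher in the stressed library. SLC17A7, the vesicular glutamate carrier of cortical neurons (ENSCAFG00000003665, chromosome 1, 107054145 to 107064065), read 203 against 0.518 FPKM (log2 7.07, counting interval of the read ratio 8.03 to 9.28). CAMK2A, a synaptic kinase, read 131 against 0.837 (log2 6.17) and CCK, a neuropeptide of the cortex, 152 against 0.307 (log2 6.87). NEUROD6, a transcription factor of cortical projection neurons, held 621 reads against 0, and TBR1, another, 365 reads against 0. The glial gene GFAP read 163 against 8.40 FPKM and the myelin gene MBP 271 against 73.3, and 15 of 19 listed neural, glial and posterior-lobe genes were higher (median log2 1.36). Lymphocyte genes were higher in 15 of 16 cases (median log2 0.83), and the chemokines CCL5 and CXCL10 read 138 against 6.68 and 105 against 9.71, while macrophage and neutrophil genes were 7 higher and 8 lower (median log2 -0.02). Most hormone genes were lower (6 of 7, median log2 -0.59), with POMC at 10150 against 30310 FPKM (log2 -1.58, counting interval -1.59 to -1.57), LHB at 4603 against 8871, TSHB at 203 against 413, PRL at 11160 against 15850 and PAX7 at 1.33 against 10.0, while GH1 stood at 81840 against 79000. Pituitary lineage factors were lower in 13 of 14 cases (median log2 -0.62). Corticotroph genes (median log2 -0.02), pituitary receptors (-0.01) and secretory-granule genes (0.01) lay inside the range of random lists. SCTR, the secretin receptor, had the lowest log2 ratio among genes with at least 100 reads, -2.96.

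**Figure D2:**
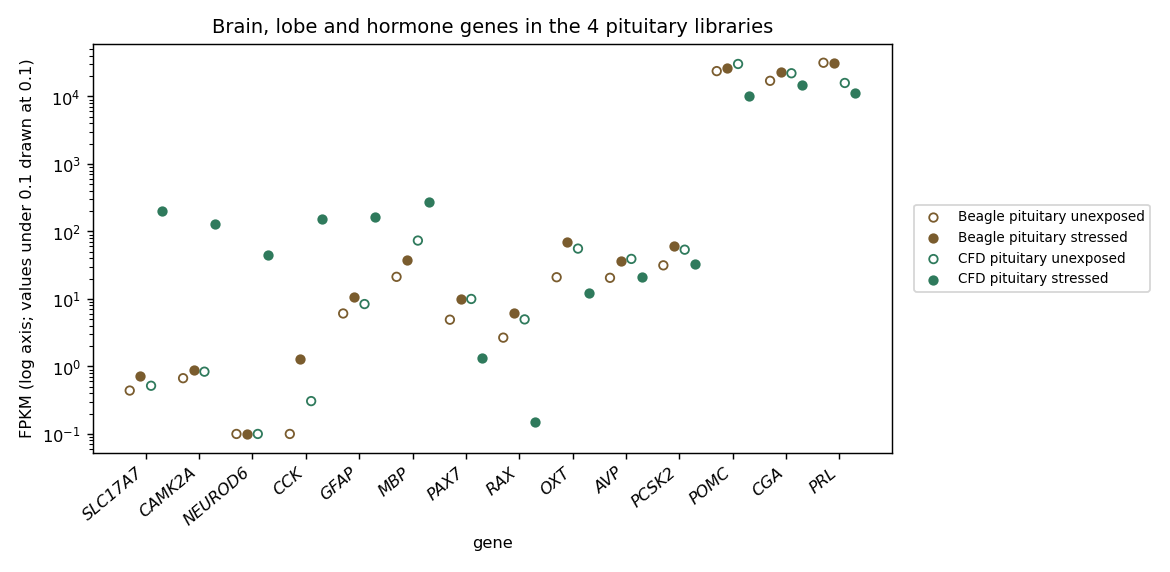
Level of 14 genes in FPKM (vertical log axis, values under 0.1 drawn at 0.1) in the 4 pituitary libraries, 1 point per library; CFD is Chinese Field Dog. SLC17A7, CAMK2A, NEUROD6 and CCK stand at 203, 131, 45.2 and 152 FPKM in the stressed Chinese Field Dog and at 1.28 or below in the other 3 libraries, and POMC stands at 10150 there against 23760 to 30310 elsewhere.

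Across both breeds, interferon-response genes stood higher in the stressed pituitaries (medians 0.80 in the Beagle and 0.54 in the Chinese Field Dog), as did the neural, glial and posterior-lobe list (0.81 and 1.36), although the posterior-lobe genes OXT (log2 -2.08) and AVP (log2 -0.84) were lower in the Chinese Field Dog. ISG15, a ubiquitin-like protein made on interferon exposure (ENSCAFG00000019348, chromosome 5, 56230817 to 56237586), read 56.2 against 15.5 FPKM in the Beagle and 102 against 36.8 in the Chinese Field Dog, a limma log2 of 1.62 (SE 0.17, adjusted p over all genes 0.861). IFI44 read 42.1 against 20.7 and 57.1 against 35.2, and the antiviral GTPase gene MX1 123 against 70.9 and 160 against 114. Of 24 measured interferon genes 23 were higher in both breeds, with a median log2 of 0.64, and 16 passed when limma's p-values were adjusted over the list alone, against 0 over all genes. That count depends on both ratios and on the pooled spread: it was 8 without the Chinese Field Dog ratio, 0 without the Beagle ratio and 0 with 1 fit per tissue, while edgeR gave 18 and DESeq2 14. Lymphocyte genes had a median log2 of 0.83 in the Chinese Field Dog and -0.01 in the Beagle, and macrophage and neutrophil genes -0.02 and 0.33 (10 of 14 higher in the Beagle), differences that were not tested. The oligodendrocyte transcription factors OLIG1 and OLIG2 (log2 1.27) also passed when adjusted over the list alone, with 0 calls over all genes. The neural and glial list had 15 calls without the Beagle ratio and 0 without the Chinese Field Dog ratio. Single genes that passed over their lists alone were ANGPTL4 (lower, log2 -0.95, a lipase inhibitor induced by fasting), the chemokine CCL2 (log2 1.11), CYP17A1 (log2 0.93, on 251 reads at most), RSPO3 (log2 1.28) and SLC18A1 (lower, log2 -0.90). Without the Chinese Field Dog ratio each of those 5 lists had 0 calls. Without the Beagle ratio the glucocorticoid list of ANGPTL4 and the medulla list of SLC18A1 had 1, both higher, the inflammatory list of CCL2 had 5 and the others 0. DLK1, a growth regulator of the anterior pituitary, was lower in both breeds at 7.14 against 19.4 and 3.74 against 15.99 FPKM (limma log2 -1.58, adjusted p 0.861). Over all 14722 genes limma called 1, an unnamed gene on 1 read, with 703 at an unadjusted p under 0.05 against 736 expected; the count was 61 without the Beagle ratio and 42 without the Chinese Field Dog ratio, 0 by edgeR (830 at an unadjusted p under 0.05) and 65 by DESeq2.

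The next question was how the breeds differed, within each tissue and exposure. Genes at least 2-fold different between Chinese Field Dog and Beagle numbered 598 of 13744 in the unexposed adrenal cortex (227 higher in Chinese Field Dog, 371 lower), 409 of 13626 in the stressed adrenal cortex (228 higher, 181 lower), 498 of 14460 in the unexposed pituitary (290 higher, 208 lower) and 1631 of 14670 in the stressed pituitary (1280 higher, 351 lower). With at least 50 reads required the counts were 432, 239, 325 and 1422. GH1 and RRBP1 are again among the 498 through the failed estimate. The 1405 and 1631 include forebrain genes of the stressed Chinese Field Dog library such as SLC17A7.

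In the adrenal cortex, macrophage and antigen-presentation genes were higher in the Chinese Field Dog under both exposures. MARCO, a scavenger receptor of macrophages (ENSCAFG00000004913, chromosome 19, 30996185 to 31034536), read 9.74 against 0.197 FPKM in the unexposed and 7.76 against 0.177 in the stressed libraries and passed limma's test over all genes (log2 3.03, SE 0.14, adjusted p 0.034). CD5L, a protein secreted by tissue macrophages (ENSCAFG00000016447, chromosome 7, 40515317 to 40526634), read 21.3 against 0.549 and 20.6 against 0.325 (log2 3.93, SE 0.20, adjusted p 0.0373). HAO2, a peroxisomal oxidase of hydroxy acids (ENSCAFG00000010027, chromosome 17, 56505359 to 56528739), read 387 against 56.8 and 267 against 46.0 (log2 2.63, SE 0.14, adjusted p 0.0373). B2M, the light chain of class I molecules, read 5298 against 2230 and 4635 against 2245 FPKM, and DLA-79, a canine class I gene, 82.4 against 13.7 and 95.4 against 8.82. The killer-cell protease GZMB read 20.5 against 2.75 and 16.4 against 0.772. With adjustment over the list alone limma called 9 of 15 antigen-presentation genes (0 over all genes) and 8 of 15 macrophage and neutrophil genes (1 over all genes), all higher. It also called 3 of 10 lymphocyte genes, GZMB, NKG7 and PTPRC, all higher (1 over all genes, NKG7, on at most 1 read per library). Without the unexposed ratio those counts were 0, 1 and 2, and without the stressed ratio 4, 1 and 2.

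Medulla genes were lower in the Chinese Field Dog adrenal cortex under both exposures, 18 of 20 in both, with a median log2 of -0.87 unexposed and -0.71 stressed. DBH read 331 against 758 and 239 against 467 FPKM, and PNMT, which makes adrenaline, 345 against 962 and 382 against 584. A different share of medulla in the sampled pieces was not tested. Of the 20 genes limma called 10 over the list alone and 0 over all genes, and leaving out either ratio brought the list count to 0; edgeR called 5 and DESeq2 9 over the list alone. Secretory-granule genes were lower in 16 of 16 cases under both exposures, with 4 called over the list alone (0 over all genes, and 0 over the list with either ratio left out). Over the list alone limma called PCSK1 and SCG5, which act in prohormone processing, among 8 corticotroph genes, both lower. Both were already among the 4 secretory-granule calls, and SCG2, another of those 4, was also among the 10 medulla calls. The lineage factors GATA2 (log2 -0.62) and ISL1 (log2 -0.70) were called lower over their list alone. HERC6, SAMD9L and TLR2 were called higher over theirs. The corticotroph, lineage-factor, interferon and inflammatory lists had 0 calls over all genes. Without the unexposed ratio each of these lists had 0 calls, and without the stressed ratio 1 corticotroph gene and 1 inflammatory gene passed, both lower. The steroid-synthesis genes had medians of -0.09 and 0.06, with 0 calls over the list alone. NPY and UCN differed in the unexposed pair, at 27.1 against 266 and 2.97 against 51.9 FPKM, and far less in the stressed pair, at 25.8 against 35.2 and 6.80 against 4.21.

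Limma called 10 of 13759 genes for breed in the adrenal cortex, 8 higher and 2 lower, with 1008 at an unadjusted p under 0.05 against 688 expected. The other 7, NKG7, SNORD14, 2 genes named SNORD22, U4 and 2 without a symbol, rested on 1 or 2 reads in their deepest library. In the simulated data for this contrast the fit made 8 calls among unchanged genes. It also recovered 2, 29, 50 and 50 of the 50 changed genes at 2-, 4-, 8- and 16-fold. How many of the 10 real calls are false cannot be read from this, since the simulated number of changed genes was set. Of MARCO, CD5L and HAO2, all 3 passed with at least 50 reads required and by DESeq2, and none by edgeR (adjusted p 0.158, 0.27 and 0.27). With no filter on low values none passed (0.0642, 0.099 and 0.0833), and with a pseudocount of 0.1 MARCO passed while CD5L and HAO2 had 0.252. With 1 fit per tissue HAO2 did not pass (0.0528), while MARCO (0.0372) and CD5L (0.0135) did, and at a mean FPKM of at least 5 MARCO was not tested. None passed without the unexposed ratio (adjusted p 0.212, 0.387 and 0.29) or without the stressed ratio (0.202, 0.478 and 0.268), where the lone ratio is taken to vary like those of the pituitary. Those fits called 40 and 37 genes in all, edgeR 0 (1255 at an unadjusted p under 0.05) and DESeq2 106.

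**Figure D3:**
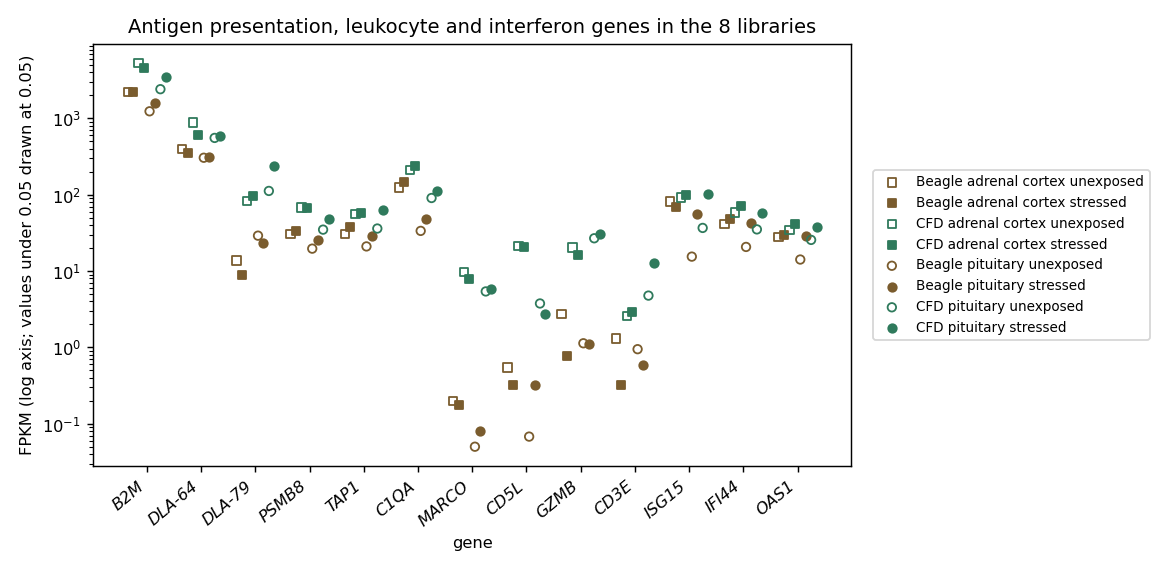
Level of macrophage, lymphocyte, antigen-presentation and interferon genes in FPKM (vertical log axis) in each of the 8 libraries, 1 point per library (squares adrenal cortex, circles pituitary; open unexposed, filled stressed), with values under 0.05 drawn at 0.05; CFD is Chinese Field Dog. MARCO, CD5L, GZMB and B2M are higher in the Chinese Field Dog than in the Beagle in both tissues and under both exposures, MARCO at 9.74 against 0.197 in the unexposed adrenal cortex.

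In the pituitary the same immune groups were higher in the Chinese Field Dog. GZMB read 26.9 against 1.13 FPKM unexposed and 30.7 against 1.10 stressed (limma log2 3.81, SE 0.23, adjusted p 0.11), MARCO 5.41 against 0.038 and 5.74 against 0.081 (log2 2.63, adjusted p 0.0772), B2M 2416 against 1240 and 3528 against 1604, and DLA-79 112 against 29.1 and 236 against 23.2. Limma called 10 of 15 antigen-presentation genes over the list alone, all 15 higher in both pairs, 11 of 15 macrophage and neutrophil genes, 9 of 13 lymphocyte genes and 12 of 24 interferon genes, with 0 over all genes for each. Without the unexposed ratio the counts were 10, 6, 10 and 0, without the stressed ratio 1, 6, 4 and 0, and with 1 fit per tissue the interferon count was 0. CCL2, CXCL10 and SOCS3 (higher) and PTX3 (lower) passed among the inflammatory genes, 6 without the unexposed ratio and 1 without the stressed ratio. FSHB, the beta chain of follicle-stimulating hormone, was the hormone gene that passed over its list (882 against 338 and 827 against 281 FPKM, log2 1.47, SE 0.14, adjusted p over all genes 0.218; 1 hormone gene passed without the unexposed ratio and 2 without the stressed one), and PRL was lower in both pairs (15850 against 31610 and 11160 against 31810) without passing. The myelin and glial genes MAG, MBP, MOG and OLIG1 passed over the list alone, with 0 calls over all genes; the list had 17 calls without the unexposed ratio and 4 without the stressed ratio. CYP11A1, CYP17A1 and CYP21 passed among the steroid genes, at levels of at most 6.81 FPKM for CYP17A1, and WNT4 and the haemoglobin gene HBA (lower, 22.6 against 85.6 and 33.3 against 89.8) passed alone in their lists; with either ratio left out, neither passed, and the steroid count was 2. Among genes outside the lists, C16orf89, a secreted protein, read 23.0 against 0.465 and 16.4 against 2.30, and GFRAL, the receptor of a stress-induced cytokine, 2.25 against 18.5 and 4.77 against 22.2.

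Over all 14722 pituitary genes limma called 4 for breed, with 1244 at an unadjusted p under 0.05 against 736 expected. That excess depended on the spread shared with the adrenal cortex, since with 1 fit per tissue limma had 696 such genes. 5S_rRNA was higher, SNORD22 and MIAT_exon5_2 were lower, each on 1 or 2 reads, and an unnamed gene (ENSCAFG00000029939) with up to 180 reads was higher (log2 4.99, adjusted p 0.0485). That unnamed gene did not pass without the unexposed ratio (adjusted p 0.058), without the stressed ratio (0.179), by edgeR (0.162) or by DESeq2 (0.663). Nor did it with a pseudocount of 0.1 (0.269), no filter (0.157), centred ratios (0.0534), 1 fit per tissue (0.192) or at least 50 reads (0.0677). Besides the reported fit, it passed only at a mean FPKM of at least 5 (0.0373) and by limma-trend (0.0406). The number of calls was 67 without the unexposed ratio, 47 without the stressed ratio, 2 by edgeR (1461 at an unadjusted p under 0.05) and 222 by DESeq2.

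The last question was whether the breeds answered the exposure alike. Across genes, the log2 stress ratios of the breeds had a Pearson correlation of -0.0376 in the adrenal cortex and -0.0149 in the pituitary, and the breed ratios of the 2 exposures had 0.054 and 0.123; these 4 correlations run across genes, which are not independent replicates. The adrenal stress value turned positive by rank (Spearman 0.079) and with at least 50 reads required (0.13). The pituitary stress value stayed near 0, at -0.0348 by rank and 0.0021 with at least 50 reads. The adrenal breed value was 0.27 by rank and 0.361 with at least 50 reads, and the pituitary breed value 0.134 and 0.284. GH1 and RRBP1 enter the pituitary correlations with their failed estimate. In the adrenal cortex 16 genes were 2-fold higher and 24 lower with stress in both breeds, against 1.09 and 3.21 if the breeds were independent. Another 14 were higher in the Beagle and lower in the Chinese Field Dog (1.12 expected) and 13 the reverse (3.11 expected). With at least 50 reads required these 4 adrenal counts were 6, 10, 1 and 5 (0.2, 1.17, 0.17 and 1.4 expected). In the pituitary 36 were higher in both (13.8 expected) and 13 lower in both (2.64 expected), and 43 were higher in the Beagle and lower in the Chinese Field Dog (3.15 expected), with 21 the reverse (11.6 expected). With at least 50 reads required these 4 pituitary counts were 26, 5, 33 and 9 (8.33, 1.19, 1.43 and 6.9 expected). For breed, 67 adrenal genes were higher in the Chinese Field Dog under both exposures (3.68 expected) and 29 lower (4.81 expected), while 14 and 18 changed side between exposures (2.93 and 6.04 expected; 1 and 9 with at least 50 reads, against 1.17 and 3.57). In the pituitary 145 were higher (25.6 expected) and 33 lower (4.77 expected) in both, while 37 and 16 changed side (7.34 and 16.6 expected). How the contrasts compare in recurrence was not tested. The difference between the breeds' log2 stress ratios was at least 1 in either direction for 688 adrenal genes and 1859 pituitary genes. The latter include the forebrain genes of 1 library, and GH1 and RRBP1 through the failed estimate in the unexposed Beagle pituitary. This difference could not be tested, since 4 libraries per tissue leave no residual degrees of freedom for it.

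Among the 30 gene lists fixed before the values were seen, 118 of 226 list medians over the 8 comparisons lay outside the middle 95% of 10000 random lists of like abundance, against 11.4 expected by chance if list members were independent, which co-expressed genes are not. In the adrenal stress comparisons, medians for Beagle and Chinese Field Dog were 0.20 and 0.09 for interferon, 0.05 and -0.14 for antigen presentation, 0.02 and -0.29 for macrophage and neutrophil, -0.20 and 0.11 for lymphocyte, 0.13 and -0.21 for immediate-early, and -0.11 and -0.08 for glucocorticoid receptor target genes. They were 0.21 and 0.25 for endothelial, -0.34 and 0.18 for fibroblast and matrix, -0.01 and 0.22 for inflammatory, -0.14 and -0.33 for proliferation, 0.04 and 0.39 for muscle, 0.04 and 0.07 for zona glomerulosa and capsule, -0.10 and 0.08 for oxidative-stress and -0.36 and -0.19 for corticotroph genes. Neural, glial and posterior-lobe genes stood at -0.84 and -0.06, secretory-granule genes at -0.37 and -0.20, and liver and kidney genes at 0.80 and 0.50. Pituitary receptors stood at -0.06 and -0.11, lineage factors at -0.18 and -0.28 and endoplasmic-reticulum stress genes at -0.13 and -0.02. In the stressed Beagle pituitary the median was -0.31 for pituitary hormone receptors and 0.17 for erythroid genes, and in the stressed Chinese Field Dog pituitary it was -0.32 for endoplasmic-reticulum stress, -0.18 for ribosomal protein (36 of 39 lower), 0.33 for respiration and 0.38 for cholesterol genes. The sex-linked list gave no median, because fewer than 3 of its genes were measured.

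**Figure D4:**
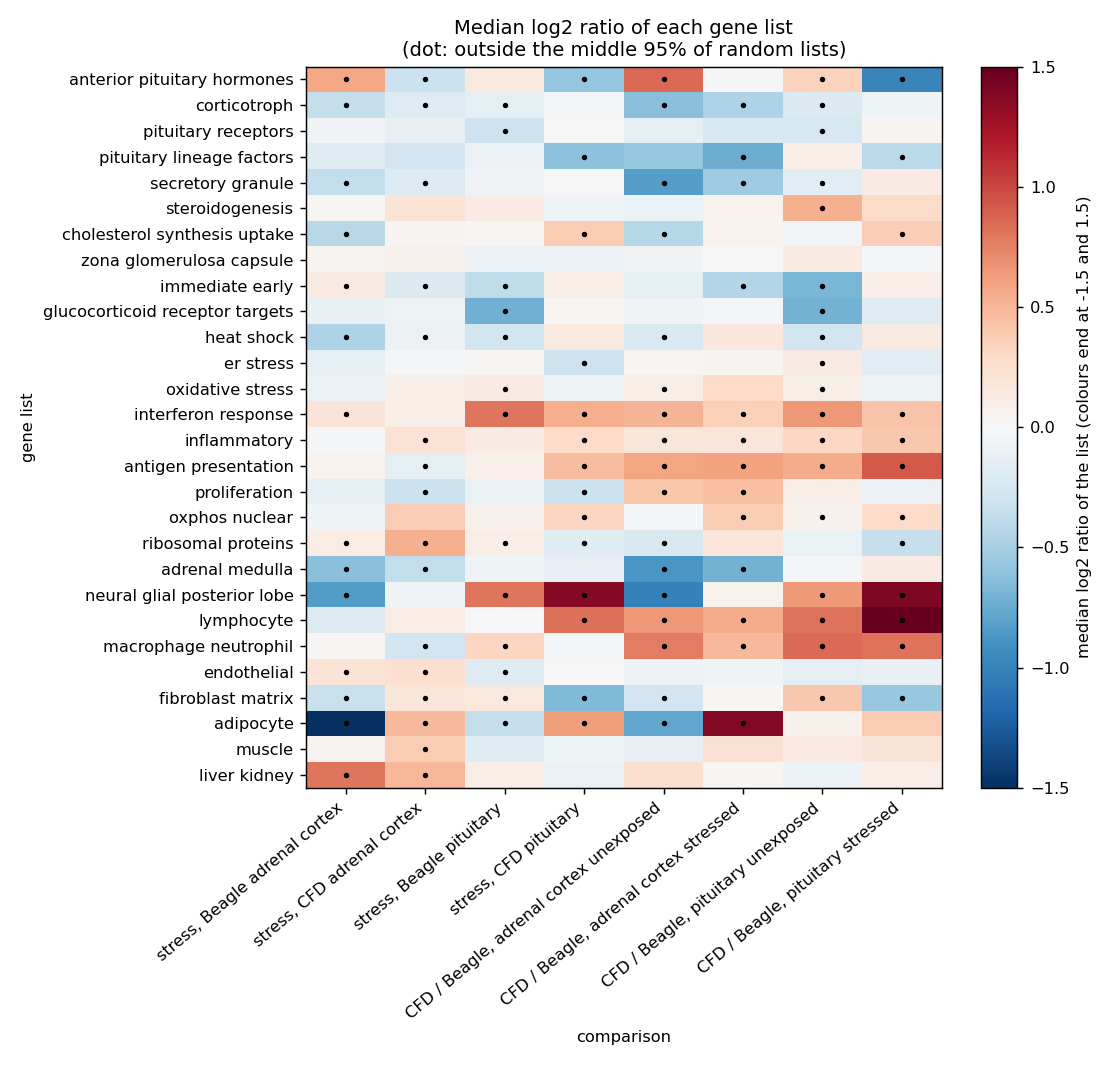
Median log2 ratio (colour scale, ending at -1.5 and 1.5) of each gene list (vertical axis) in the 8 comparisons (horizontal axis), with a dot where it lay outside the middle 95% of random lists; CFD is Chinese Field Dog. Interferon genes stood at 0.80 and 0.54 in the stressed Beagle and Chinese Field Dog pituitary, and medulla genes at -0.63 and -0.37 in the stressed adrenal cortex.

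The authors' deposited table marked as different 70, 51, 40 and 346 genes for stress in the Beagle adrenal cortex, Chinese Field Dog adrenal cortex, Beagle pituitary and Chinese Field Dog pituitary. For breed it marked 84 and 57 in the unexposed and stressed adrenal cortex and 69 and 376 in the unexposed and stressed pituitary. A rule of a p-value of at most 0.05 and at least 2-fold change departed from these marks for 5, 5, 2, 16, 8, 11, 8 and 17 genes in that order. At an FDR under 0.05 the table held 6, 5, 0 and 15 genes for stress and 6, 5, 3 and 22 for breed. Of the marked genes 36, 37, 23, 36, 34, 35, 23 and 35 had fewer than 10 reads in both libraries.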

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

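All tests of explanations in this part were chosen only after the result was seen. The groups in the next paragraphs on the adrenal cortex and the pituitary drew attention because their median log2 ratios lay on opposite sides of 0 in the breeds or exposures compared, both outside the middle 95% of random lists. None of these differences was tested.

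In the adrenal cortex, fat-cell genes had a median stress log2 of -1.55 in the Beagle and 0.49 in the Chinese Field Dog, a difference of 2.04. Their breed medians were -0.78 unexposed and 1.39 stressed, 2.16 apart. Fibroblast and matrix genes stood at -0.34 in the Beagle and 0.18 in the Chinese Field Dog (difference 0.52), and immediate-early genes at 0.13 and -0.21 (difference -0.34). Anterior pituitary hormone genes, which the adrenal cortex holds at low levels, stood at 0.58 and -0.32 (difference -0.90). The unexposed Beagle library enters both the Beagle stress ratio and the unexposed breed ratio. Medulla, fat or other tissue in the adrenal pieces was not tested and cannot be told apart from an effect of exposure or breed.

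In the pituitary, fibroblast and matrix genes had a stress median of 0.16 in the Beagle and -0.66 in the Chinese Field Dog (difference -0.82), fat-cell genes -0.36 and 0.63 (difference 0.99) and ribosomal protein genes 0.10 and -0.18 (difference -0.28). Between breeds, anterior pituitary hormone genes stood at 0.35 in the unexposed and -0.99 in the stressed pair (difference -1.34), with the failed GH1 estimate in the first, whose median was 0.22 without GH1. Fibroblast and matrix genes stood at 0.40 and -0.56 (difference -0.97).

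Forebrain neuron genes in the stressed Chinese Field Dog pituitary may come from brain tissue in the sampled piece. The cortical neuron list, written after the values were seen, had a median log2 of 3.51 over 9 genes (1.79 to 5.76) without the 4 already ranked. A gene near 0 in the unexposed library passed the filter of a mean of 1 FPKM only if it was high in the stressed one. That median is therefore no independent test of brain tissue. The neural and glial list, fixed earlier, had a median of 1.36. SLC17A7 stood at 203, CAMK2A at 131, GFAP at 163 and MBP at 271 FPKM. Of the 14 neuron genes, 4 reached a mean of 1 FPKM in the Beagle pituitaries. A larger share of the posterior lobe was excluded by its own genes, with a median of -1.46, and a response shared by both breeds by the Beagle median of 0.22. A response to the exposure in the Chinese Field Dog alone stays open and untested, and every pituitary comparison with that library carries these genes.

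Glucocorticoid-responsive genes such as ERRFI1, PDK4 and FKBP5 were higher in the unexposed than in the stressed Beagle pituitary. The authors' scaling by 1 factor per library was excluded, since it moves all genes alike, while the list stood at -0.72 and the middle 95% of random lists of like abundance reached down to -0.12. A larger share of the anterior lobe was excluded by the hormone genes without GH1, with a median of 0.14. Exchanged labels of the 2 Beagle pituitaries cannot be told apart from the rest, because the list stood at 0.03 in the Chinese Field Dog pituitary and that test assumed like responses. Interferon genes (22 of 23 and 24 of 24) and the mitochondrial share (5.41% against 3.96%, 7.66% against 4.55%) were higher with stress in both breeds as labelled. Fibroblast and matrix, fat-cell and ribosomal protein genes went opposite ways in the breeds. Either reading rests on the same assumption, so neither decides the question. An effect of the exposure stays open and untested, as does other tissue in the unexposed piece, where the airway genes BPIFA1 and SCGB1A1 were also higher.

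Genes of the intermediate and posterior lobes lay in opposite directions, higher in the stressed Beagle pituitary and lower in the stressed Chinese Field Dog pituitary in 8 of 9 cases. OXT had log2 ratios of 1.69 and -2.08, PAX7 0.91 and -2.24 and RAX 0.99 and -2.38, while POMC (0.16 and -1.58) and DRD2 (0.09 and -0.96) were barely higher in the Beagle, where the melanotroph median of 0.16 lay inside random lists, and TBX19 was lower in both (-0.08 and -0.74). Another share of these lobes in the pieces could explain this. One dilution of all pituitary cells would move hormone genes alike, but in the stressed Chinese Field Dog pituitary they spanned 1.63 in log2. The low end was POMC, itself among the 9 genes, yet LHB and TSHB were also lower while GH1 was near its unexposed level. Dilution alone therefore does not account for the hormone values, although 1 library per group cannot separate it from other differences between samples. A breed-specific response of these lobes stays open and untested.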

How the results depend on the processing

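The filter of at least 50 reads, edgeR, DESeq2 and the settings applied to list calls, single genes and the breed by stress difference were chosen only after the result was seen. Of 124 values for the main results under other settings, 79 stayed close, 43 moved and 2 reversed; of 888 list medians 833, 53 and 2 did so, and of 298 ratios of named genes 270, 28 and 0.

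With at least 50 reads required, genes 2-fold different with stress numbered 281 in the Beagle and 126 in the Chinese Field Dog adrenal cortex and 194 in the Beagle pituitary. Between breeds they numbered 239 in the stressed adrenal cortex and 325 in the unexposed pituitary. That filter leaves out short genes on few reads by its construction. With a pseudocount of 0.1 the count was 450 for stress in the Chinese Field Dog adrenal cortex and 548 in the Beagle pituitary, and 682 and 801 for breed in the stressed adrenal cortex and unexposed pituitary, since a smaller pseudocount shrinks low values less. With a mean FPKM of at least 5 fewer genes enter, and the counts were 160 for stress in the Chinese Field Dog adrenal cortex, 257 for breed in the stressed adrenal cortex and 301 in the unexposed pituitary. The breed by stress difference reached 1 in 438 adrenal and 1238 pituitary genes there.

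Limma called 3, 1, 10 and 4 genes in the order adrenal stress, pituitary stress, adrenal breed and pituitary breed, and the settings below gave other counts; the cause was not tested. In that order they numbered 0, 0, 3 and 0 with at least 50 reads, while edgeR gave 0, 0, 0 and 2 and DESeq2 11, 65, 106 and 222. At an unadjusted p under 0.05 edgeR had 564, 830, 1255 and 1461 genes, and limma 479, 703, 1008 and 1244. With 1 fit per tissue limma had 753, 329, 1440 and 696, against 688, 736, 688 and 736 expected by chance. With no filter on low values limma called 1 for adrenal stress, 4 for adrenal breed and 2 for pituitary breed, with a pseudocount of 0.1 it called 2 for pituitary stress, and with 1 fit per tissue 5 and 0 for adrenal and pituitary stress. Leaving out 1 ratio gave 30 to 40, 42 to 61, 37 to 40 and 47 to 67 calls in that order, where the lone ratio is taken to vary like those of the other tissue.

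The correlation of adrenal stress ratios between breeds was -0.0376, and turned to 0.079 by Spearman and 0.13 with at least 50 reads. The adrenal breed correlation was 0.27 by Spearman and 0.361 with at least 50 reads, and the pituitary breed correlation 0.284 with at least 50 reads; the cause was not tested. Proliferation genes of the Chinese Field Dog adrenal cortex went from -0.33 to 0.0526 with stress at a mean FPKM of at least 5, where 4 genes were left, and liver and kidney genes from 0.50 to -0.0816, where 3 were left. Depth limits 2-fold counts, since 111 to 117 of the genes counted per stress comparison had fewer than 10 reads in both libraries.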

Other observations

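The single genes, the mitochondrial shares and the 9 gene lists named below as written later were chosen only after the result was seen. Mitochondrially encoded genes took a larger share of recovered reads in all 4 stressed libraries than in their unexposed partners. In the adrenal cortex the share was 13.9% against 10.4% in the Beagle (Wilson 95% interval of the unexposed library 10.4257 to 10.4559) and 14.5% against 10.5% in the Chinese Field Dog. In the pituitary it was 5.41% against 3.96% in the Beagle and 7.66% against 4.55% in the Chinese Field Dog. Airway genes were highest in 1 of the 4 pituitary libraries. BPIFA1, an airway secretion gene, read 10.9 FPKM in the unexposed Beagle pituitary against 0.235 in the stressed one, and SCGB1A1, the club-cell secretoglobin, 55.0 against 5.47. In the Chinese Field Dog pituitary BPIFA1 read 0.142 unexposed and 0.257 stressed, and SCGB1A1 3.11 and 1.32.

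Among the 4 adrenal libraries, the unexposed Beagle held the highest levels of several nerve and melanocortin genes. PRPH, a neuronal filament, read 92.3 FPKM there and 10.9 in the stressed Beagle, 13.8 in the unexposed and 7.77 in the stressed Chinese Field Dog. MRAP, the partner of the receptor for adrenocorticotropic hormone, read 407, 133, 252 and 162 in the same order, and KIF1A, an axonal motor, 12.7, 4.32, 5.13 and 1.90. CORIN read 3.91 unexposed and 20.3 stressed in the Beagle against 10.4 and 3.83 in the Chinese Field Dog, and TNMD 14.2 and 2.21 against 9.90 and 54.4. In the pituitary NPY read 1.64 and 11.8 in the Beagle and 7.55 and 114 in the Chinese Field Dog, and the glial gene S100B 0.505, 5.11, 2.37 and 83.8 on 1, 10, 5 and 163 reads.

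Of the lists written later, cortical neuron genes had a median stress log2 of 4.35 in the Chinese Field Dog pituitary and 0.22 in the Beagle pituitary, and hypothalamic neuropeptide genes 1.41 and 0.23. Posterior-lobe genes stood at -1.46 and 1.01, melanotroph genes at -0.96 and 0.16. Hepatocyte genes had adrenal stress medians of 0.65 in the Beagle and 2.04 in the Chinese Field Dog. T and natural killer cell genes stood at 1.18 with stress in the Chinese Field Dog pituitary and at -0.15 in the Beagle pituitary. Between breeds, in the unexposed and stressed adrenal cortex, macrophage genes stood at 0.87 and 0.59, class I antigen genes at 1.0 and 0.86 and class II genes at 0.40 and 0.08. In the unexposed and stressed pituitary the breed medians were 1.18 and 1.01 for macrophage, 1.48 and 2.42 for T and natural killer cell, 0.82 and 1.0 for class I and 0.32 and 0.85 for class II genes.

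Of the lists fixed earlier, breed medians in the unexposed and stressed pituitary were 0.66 and 0.43 for interferon, 0.81 and 1.71 for lymphocyte, 0.85 and 0.81 for macrophage and neutrophil, and 0.64 and 1.40 for neural and glial genes. They were -0.70 and -0.19 for glucocorticoid receptor targets, -0.68 and 0.10 for immediate-early, -0.29 and 0.14 for heat-shock and -0.10 and -0.35 for ribosomal protein genes, and 0.54 and 0.28 for steroid synthesis at low FPKM. None of these medians carries a test.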
